A study of Caenorhabditis elegans with 15 samples.

How the data were processed

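RNA from whole young adult worms was measured on 15 Affymetrix C. elegans arrays in 5 groups of 3: input, anti-MYC IP and anti-FLAG IP of the tagged strain (set 1), and anti-FLAG IP of N2 and of the tagged strain (set 2). Groups and replicate numbers were taken from the sample titles, and 0 columns of the value table were without a sample. Which set the inputs belong to is not stated. Per the labels, 10 µg of mouse brain RNA was added to each IP, and 5 µg of each input or 1/3 of each IP was amplified once and labelled.

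The deposited values are on the log2 scale, 1 per probe set and array, and per the labels the authors made them with GCRMA, a background adjustment and probe set summary whose version is not stated. The deposited values were not on a common distribution: each array kept its own lowest value, which 4261 to 6723 probe sets shared exactly, and its own quartiles. On the IP arrays 54.24 to 67.75% of probe sets lay within 0.1 of the lowest value, against 36.36 to 41.21% on the inputs. The mean of the 18 hybridization control probe sets was 7.431 to 8.582 on the 15 arrays. Pearson r between replicate arrays across probe sets was 0.972 to 0.995 in input, 0.879 to 0.948 for MYC, 0.884 to 0.966 for FLAG in set 1, 0.929 to 0.948 for N2 and 0.983 to 0.985 for tagged FLAG in set 2. Between control and tagged FLAG IP arrays it was 0.602 to 0.879. No pseudocount, filter or further normalization was applied for the results of the report.

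Of 22625 probe sets, 77 array controls were left out and 22548 tested. The platform annotation gave 20766 of these 1 gene symbol, 887 several and 895 none. Entrez IDs matched 20701 probe sets to the RefSeq gene table of WBcel235, which gave positions and changed 0 symbols. A gene was represented by the probe set of its own with the highest mean over all arrays (17118 genes). The array maker marks 6711 tested probe sets, by a suffix of _x_at or _s_at, as sharing sequence with other transcripts.

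Linear models were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, group means and contrasts, two-sided moderated tests). The strategies, their difference (strategy 1 minus strategy 2), the FLAG IP sets (set 1 minus set 2) and the controls (MYC minus N2) came from 1 fit of the 12 IP arrays, with 8 residual and 0.849 prior degrees of freedom. The comparisons of set 1 IPs with input came from a fit of all 15 arrays (10 and 0.904). P-values were adjusted by Benjamini and Hochberg over the 22548 probe sets of each contrast and called under 0.05. Errors of differences are standard errors from the fit, and errors of group values are SDs. Each count of probe sets higher in both strategies was compared with that of independent lists of the same lengths.

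The 18 gene lists, written from general knowledge of C. elegans biology, were tested per strategy with camera at an inter-gene correlation of 0.01 on 1 probe set per gene, and with an estimated correlation and fry as alternatives, adjusted over the lists. Listed genes with no probe set of their own were left out: puf-6, larp-1, zyg-12, mat-2, mes-6, gpr-1, spe-42, vit-3, dpy-10, cco-1 and cco-2. Named genes were gld-1, every earlier known target, the 8 genes with the largest and the 4 with the lowest mean change called in both strategies with no overlap of arrays, the 3 highest and 2 lowest called in 1 strategy alone, the 2 largest called members of each other list and strategy (or the 2 largest changes where none was called), and the 3 highest and 3 lowest in each comparison with input. A few others given as examples of a list are the called members themselves. Comparisons, lists, the naming rule and the alternatives were fixed before the data were examined, except for 3 alternatives named in the closing section.

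Alternatives were the replicate number as a block, the 6 arrays of a comparison or all 15 arrays in the fit, filters at log2 5 and log2 7 on at least 3 arrays, quantile normalization, centring on array medians or on ribosomal protein genes, cyclic loess, a mean-variance trend with robust eBayes, adjusted p under 0.01, at least 2-fold, treat against 1.5-fold, 1 probe set per gene, the mean of a gene's probe sets, leaving out probe sets of shared sequence, array weights, set 2 IPs against input, and each replicate left out in turn. Groups of 3 also allow 10 splits of 6 arrays, so an exact two-sided permutation test of 3 against 3 cannot go below p = 0.1.

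The fit was tested on simulated data with 50 changed probe sets per fold among 22548. The changed ones were drawn only from the 1627 that had reached log2 5 on 3 IP arrays, so recovery among dimmer probe sets was not tested. With the lowest value of each array kept, 4, 16, 26 and 50% of 2, 4, 8 and 16-fold changes were recovered in strategy 1, with 5 false calls among 22348 unchanged probe sets, and 0, 6, 18 and 56% in strategy 2, with 1 false call. The comparisons of the FLAG and MYC IPs with input gave 8835 and 9045 false calls in this simulation, and 2 and 2 when no lowest value was imposed on the simulated arrays. The simulated noise was independent between genes, unlike that of real arrays. Among the 1627 simulated probe sets that had reached log2 5 on 3 IP arrays, camera called the raised list in each of these comparisons and 0 of 10 unchanged lists. This is not the gene number of the list tests of the report. Tables were handled in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, and figures drawn with matplotlib 3.10.9.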

Results

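RNA that came down with the RNA-binding protein GLD-1 was measured on Affymetrix C. elegans expression arrays. GLD-1 is a STAR-family translational repressor of the hermaphrodite germline. Whole young adult worms carried gld-1(q485), a mutant allele of the gene, together with ozIs2, an integrated transgene that encodes GLD-1 fused to GFP and the FLAG tag. There were 15 arrays in 5 groups of 3 replicates. A first set of immunoprecipitations (IPs) from the tagged strain held 3 anti-FLAG IPs and 3 IPs with an anti-MYC antibody, for which this strain carries no tag. A second set held 3 anti-FLAG IPs from the tagged strain and 3 anti-FLAG IPs from wild type (N2), which has no FLAG tag. The other 3 arrays measured total RNA of the tagged strain before IP (input). Strategy 1 is the anti-FLAG minus the anti-MYC IP of set 1, and strategy 2 is the tagged minus the N2 anti-FLAG IP of set 2. The strategies share no array.

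The IP arrays carried far less C. elegans signal than the inputs. Probe sets at log2 5 or more numbered 7632 to 9352 on the input arrays, 194 to 820 on the MYC IP arrays, 550 to 2170 on the FLAG IP arrays of set 1, 221 to 435 on the N2 IP arrays and 1265 to 1784 on the tagged FLAG IP arrays of set 2. Transcripts of ribosomal protein genes, which are abundant and served as a measure of background RNA, had a median signal of 13.10 ± 0.134 (SD, n = 3) in input. In the IPs it was 7.87 ± 1.45 for MYC, 7.86 ± 2.05 for FLAG in set 1, 7.17 ± 0.772 for N2 and 7.32 ± 0.547 for tagged FLAG in set 2 (SD, n = 3 each). The dimmest tagged IP was FLAG replicate 1 of set 1, with a ribosomal protein median of 5.75 against 9.85 for replicate 3. The number of arrays limits the precision of every value that follows.

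**Figure D1:**
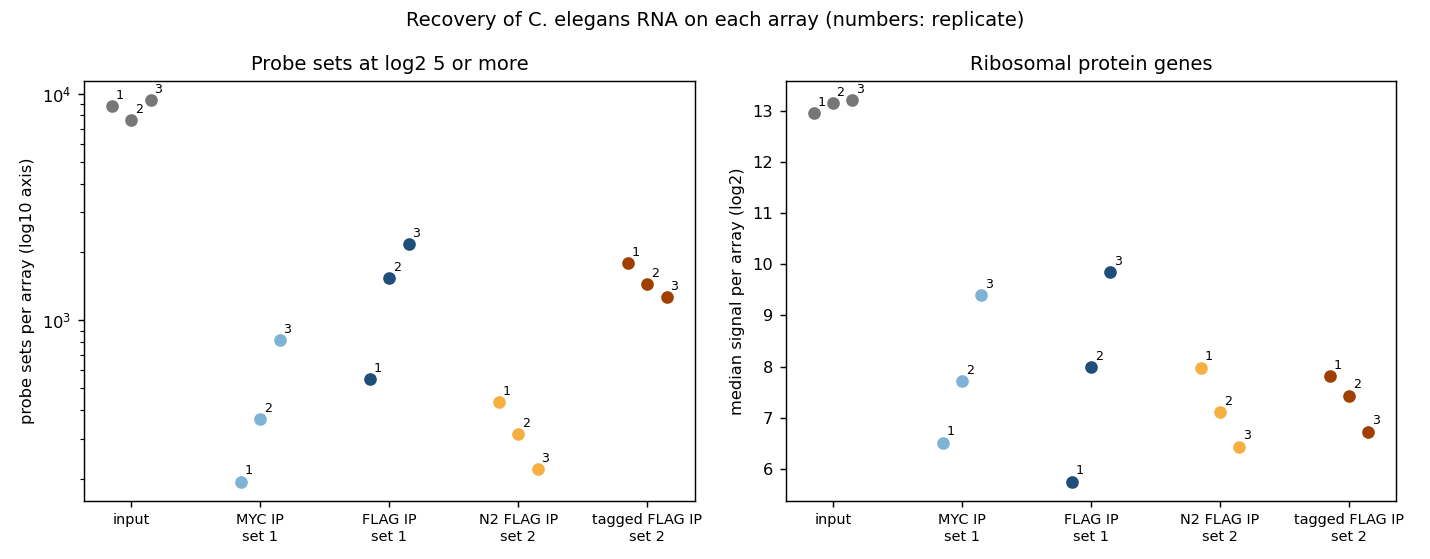
Number of probe sets at log2 5 or more (left, log10 axis) and median log2 signal of ribosomal protein genes (right) on each of the 15 arrays, 1 point per array, labelled with its replicate number. FLAG IP replicate 1 of set 1 had 550 probe sets at log2 5 or more, against 1528 and 2170 on the other FLAG arrays of that set.

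The transcript of the tagged gene, gld-1 (chromosome I, 7695681 to 7698222 in WBcel235, probe set 174247_at), was higher in the FLAG IP in both strategies. Its signal was 3.65 ± 0.914 in the MYC IP and 9.13 ± 0.731 in the FLAG IP of set 1, a difference of 5.48 ± 0.575 (SE) or 44.7-fold (adjusted p = 0.00231). In set 2 it was 4.62 ± 0.855 in the N2 IP and 10.17 ± 0.298 in the tagged IP, a difference of 5.55 ± 0.575 or 46.8-fold (adjusted p = 0.000945; group values as log2 mean ± SD, n = 3). The strategy 1 call ended when the spread came from the 6 arrays of that comparison alone, and the strategy 2 call after cyclic loess. In input gld-1 stood at 9.82 ± 0.711. A second gld-1 probe set, 193805_at, read only 3.40 in input and was not called in either strategy (0.35, adjusted p = 0.322, and 0.51, adjusted p = 0.144).

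Strategy 1 asked which transcripts the anti-FLAG antibody recovered beyond an antibody with no target in the same strain. Transcripts with the largest changes included oma-2, which encodes a zinc finger protein needed for oocyte maturation (chromosome V, 8029439 to 8031214; 6.65 ± 0.592, 100-fold, adjusted p = 0.00149), and cpg-2, which encodes an eggshell chondroitin proteoglycan (chromosome III, 7102090 to 7103990; 5.89 ± 0.699, 59.2-fold, adjusted p = 0.0037). The yolk receptor gene rme-2 (chromosome IV, 5470027 to 5473174) was 43.2-fold higher (5.43 ± 0.616, adjusted p = 0.00322), and gna-2, whose product makes a precursor of eggshell chitin (chromosome I, 7699543 to 7700958), 40.8-fold (5.35 ± 0.485, adjusted p = 0.00156). In all, 543 of 22548 probe sets, for 441 genes, were higher at adjusted p under 0.05, with a median change of 3.29 (9.81-fold). Of the 543, 523 changed at least 2-fold, and 18 had a control group within 0.1 of the lowest value on all 3 arrays, so that their folds may be lower bounds. The 13 probe sets called lower, such as T22H2.4 (fell by 0.295) and Y39A3A.2 (fell by 0.284), changed by at most 0.295 on the log2 scale, and 12 of them lay under log2 3 in both groups. After quantile normalization 685 were higher and 350 lower, and after cyclic loess 491 and 366, so the share of lower calls depends on the scaling. The number called higher was 2090 without FLAG replicate 1, 196 without MYC replicate 2, 221 without MYC replicate 1, 206 without FLAG replicate 2 and 216 without FLAG replicate 3. It was 0 when the spread came from the 6 arrays of this comparison alone (unadjusted p under 0.05 in the limma fit reported here: 1921 higher, 890 lower), 933 among the 1627 probe sets that reached log2 5 on 3 IP arrays, 199 with arrays centred on ribosomal protein genes and 6224 with fitted array weights, which called more probe sets lower, 12432.

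Strategy 2 asked the same of the tag itself, with one antibody on extracts with and without tagged GLD-1. The transcripts with the largest changes again included oma-2 (8.17 ± 0.592, 287-fold, adjusted p = 0.000335), rme-2 (6.75 ± 0.616, 108-fold, adjusted p = 0.000549) and gna-2 (6.63 ± 0.485, 98.9-fold, adjusted p = 0.000335), together with egg-1, which encodes an oocyte surface protein needed at fertilization (chromosome III, 5728180 to 5730159; 7.17 ± 0.751, 144-fold, adjusted p = 0.000985). The Aurora A kinase gene air-1 was 30.2-fold higher (4.92 ± 0.941, adjusted p = 0.0162) and passed the threshold in this strategy but not in strategy 1 (3.86 ± 0.941, adjusted p = 0.0866). The test of that difference had an adjusted p of 0.997. In all, 1233 probe sets for 987 genes were higher, with a median change of 2.84 (7.15-fold). Of these, 1132 changed at least 2-fold, and 95 had a control group within 0.1 of the lowest value on all 3 arrays. The 39 called lower, among them ZK1128.3 (fell by 0.373) and prx-10 (fell by 0.323), changed by at most 0.373, with 38 under log2 3 in both groups. Quantile normalization gave 962 higher and 579 lower, and cyclic loess 998 and 598. The number called higher was 830, 750 and 689 without N2 replicates 1, 2 and 3, and 669, 808 and 1011 without tagged replicates 1, 2 and 3. It was 2601 from the 6 arrays alone, 385 after centring on ribosomal protein genes and 3195 with array weights. The balance turned to lower calls with the 6 arrays alone (6460 lower) and with array weights (7995 lower). It also did with the replicate number as a block (2626 higher, 5529 lower), which assumes pairs that the labels do not state. The lowest value was 2.513 to 2.527 on the N2 IP arrays and 2.471 to 2.486 on the tagged IP arrays. A probe set at the lowest value of every array of set 2 therefore had a small negative change. How many of these lower calls lay there was not counted, so they do not by themselves show a loss from the tagged IP.

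Probe sets higher in both strategies numbered 526, for 426 genes, 17.71 times the 29.69 that independent lists would share. That ratio is a description and no test. Both strategies use the same spread per probe set from 1 fit, which by itself makes shared calls more likely. Among the 1627 brighter probe sets they numbered 928, nearly all of the 933 called higher in strategy 1 there, against 658.9 of independent lists. Lists that long cannot share many more than independent ones, so the ratio depends on how many dim probe sets are counted. The 526 made up 96.87% of the strategy 1 list and 42.66% of the strategy 2 list. The 8 genes with the largest mean change were oma-2, egg-1, cpg-2, gln-5, which encodes a glutamine synthetase (5.85 and 6.61 in strategies 1 and 2), bir-1, which encodes a survivin-like protein of the chromosomal passenger complex (5.45 and 6.94), rmd-1 (5.74 and 6.65), dpf-3, which encodes a dipeptidyl peptidase (5.59 and 6.66), and Y54G9A.5 (5.48 and 6.73). The probe sets of oma-2, cpg-2, gln-5, dpf-3 and Y54G9A.5 share sequence with other transcripts by the array maker's suffix. The median fold of the 526 was 9.91 in strategy 1 and 17.44 in strategy 2. Of the 707 probe sets higher in strategy 2 alone, such as T01C3.3 (5.21) and F26H9.5 (4.93), 693 also had a positive change in strategy 1, and 603 had an unadjusted p under 0.05 there. The 17 higher in strategy 1 alone included C04F12.7 (3.33, adjusted p = 0.0345; in strategy 2 2.65, adjusted p = 0.0529), C33F10.1 (2.77; 1.80 in strategy 2) and ZK858.2 (2.37; 1.38 in strategy 2). Lower in both were 0 probe sets (282 after quantile normalization and 336 after cyclic loess, where those higher in both were 632 and 434). Across the 22548 probe sets, which are not independent replicates, the changes correlated at Pearson r = 0.967 and Spearman rho = 0.529, and across the 1627 brighter ones at 0.959 and 0.956. No probe set differed between the strategies in the limma test of the difference (0 called; 133 higher and 222 lower in strategy 1 at unadjusted p under 0.05). The count of 526 was 0 with the 6 arrays of each comparison alone, 191 after centring on ribosomal protein genes, 2871 with array weights and 1688 without FLAG replicate 1 of set 1. With each other array of set 1 left out it was 216 (MYC replicate 1), 193 (MYC replicate 2), 461 (MYC replicate 3), 200 (FLAG replicate 2) and 211 (FLAG replicate 3). Without an array of set 2 it was 387, 347 and 375 for N2 replicates 1, 2 and 3 and 410, 360 and 413 for tagged replicates 1, 2 and 3.

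**Figure D2:**
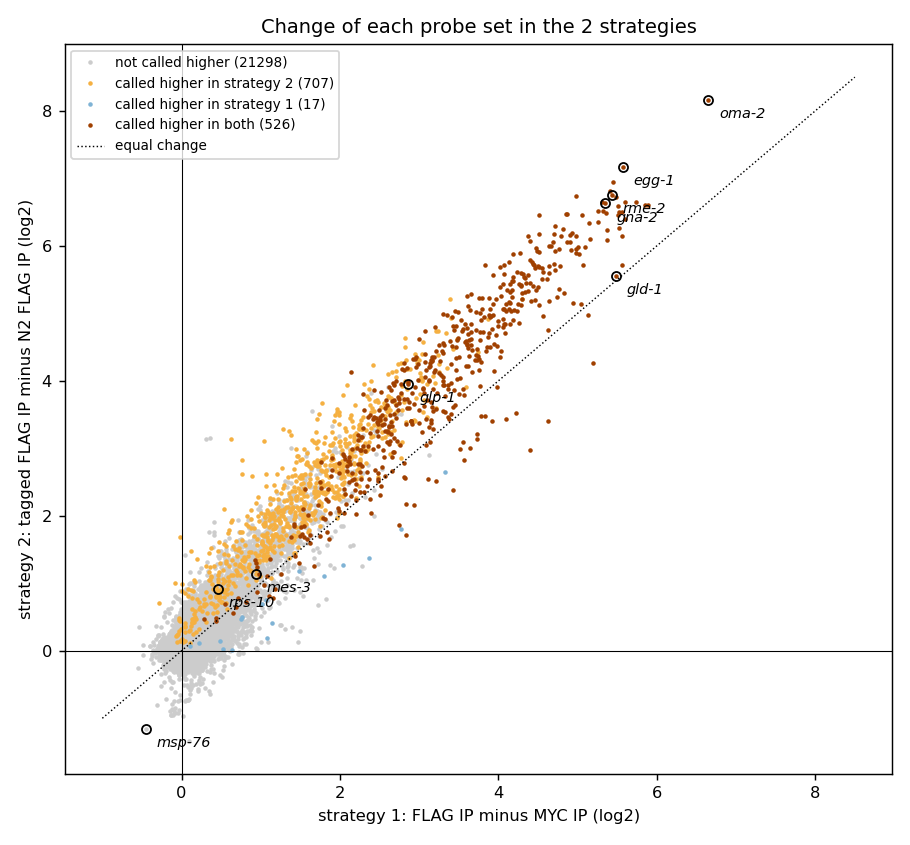
Log2 change of each of the 22548 probe sets in strategy 1 (x axis) and strategy 2 (y axis), 1 point per probe set, coloured by whether it was called higher; circles mark named genes and the dotted line marks equal change. Of the 526 probe sets called higher in both, that of oma-2 lies farthest out, at 6.65 and 8.17.

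**Figure D3:**
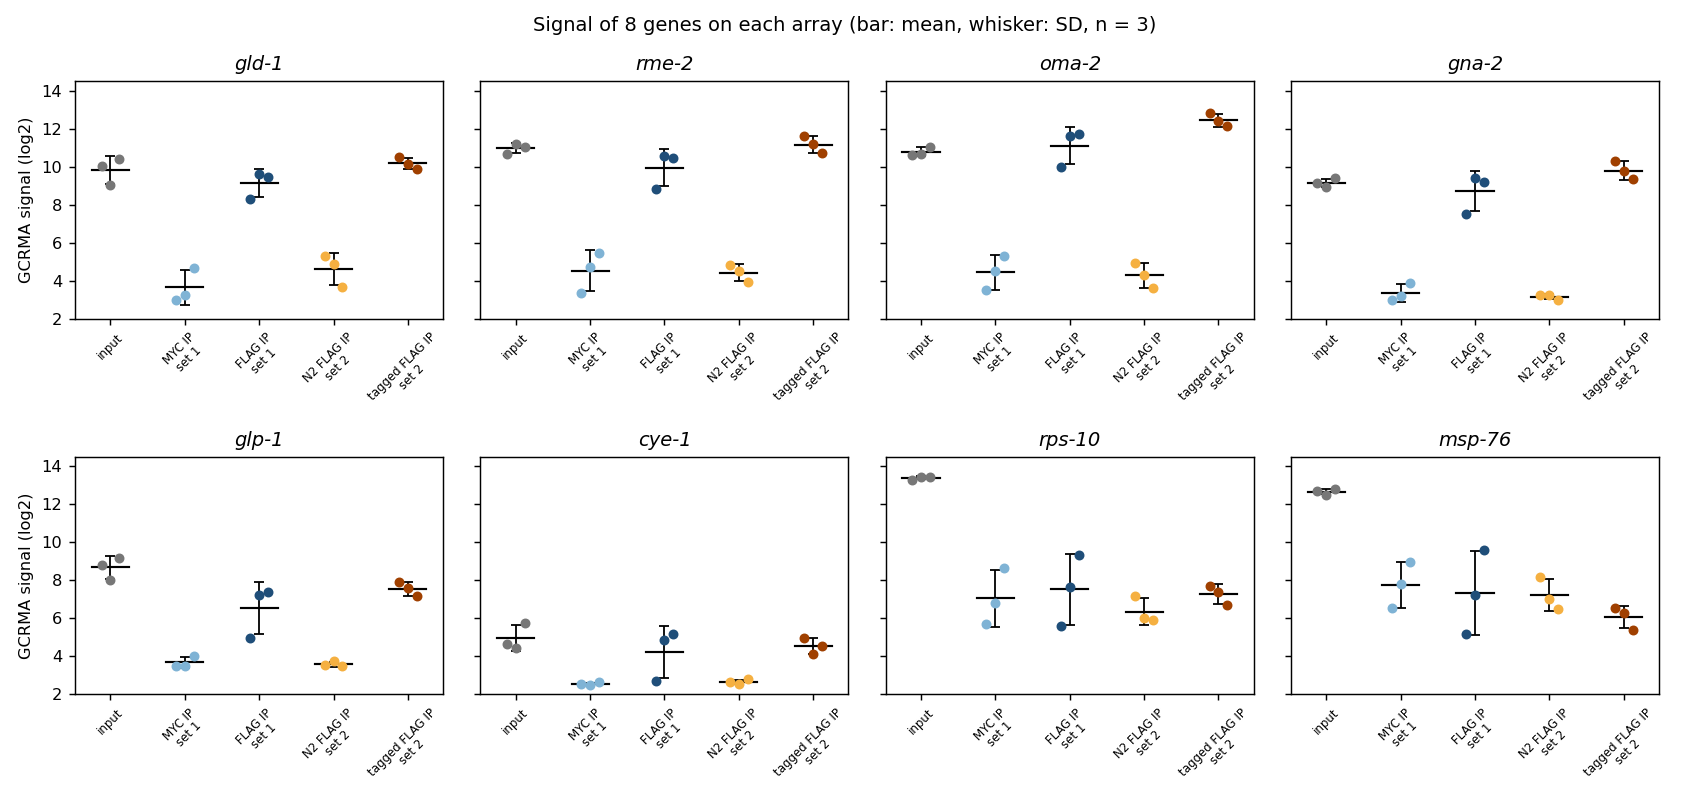
Log2 signal of 8 genes on every array, with the mean and SD of each group of 3. The signals of gld-1, rme-2, oma-2, gna-2, glp-1 and cye-1 were higher on all 3 FLAG IP arrays than on all 3 control arrays of the same set, in both sets, while those of rps-10 and msp-76 overlapped.

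Transcripts that earlier work reported as bound or repressed by GLD-1 formed the first gene list. Of its 13 measured members 10 were higher in strategy 1 and 12 in strategy 2, with 13 and 13 adjusted over the list alone and median changes of 4.51 and 5.59 (camera adjusted p = 2.14e-21 and 3.94e-19; 0.126 and 0.133 with an estimated correlation). Beside oma-2, rme-2 and gna-2 these were oma-1 (5.15 and 6.33), puf-5, a PUF family repressor gene (4.72 and 6.30), mex-3 and spn-4, genes for RNA-binding proteins of the early embryo (4.63 and 5.59; 4.51 and 5.68), pal-1, a caudal-like homeobox gene (4.25 and 5.14), the p53-like gene cep-1 (3.13 and 4.0) and the Notch receptor gene glp-1 (2.86 and 3.96). The sex determination gene tra-2 had changes of 2.77 (adjusted p = 0.0577) and 4.27 (adjusted p = 0.00417), and the chromatin regulator gene mes-3 of 0.94 (adjusted p = 0.0793) and 1.13 (adjusted p = 0.019). The cyclin E gene cye-1 passed in neither, with 1.68 ± 0.55 (adjusted p = 0.233) and 1.90 ± 0.55 (adjusted p = 0.0961). The strategy 1 calls of puf-5, spn-4, cep-1 and glp-1 ended without any one of MYC replicates 1 and 2 and FLAG replicates 2 and 3, and that of mes-3 in strategy 2 without any array of set 2 but tagged replicate 3. Without FLAG replicate 1, tra-2, mes-3 and cye-1 were called in strategy 1.

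Genes for RNA regulators of oocytes and embryos showed the same picture. Of 22 members 14 and 18 were higher in strategies 1 and 2 (17 and 20 adjusted over the list alone), with medians of 4.21 and 5.19 (camera adjusted p = 1.92e-24 and 7.05e-25; 0.126 and 0.133 with an estimated correlation). They included 4 PUF genes, puf-3, puf-5, puf-7 and puf-11, with changes of 4.18 to 4.77 in strategy 1 and 5.54 to 6.30 in strategy 2, and pie-1, which encodes a germline fate determinant (4.71 and 5.73). Of 13 genes for yolk uptake and the eggshell 9 and 10 were higher (10 and 10 adjusted over the list alone), with medians of 4.71 and 5.65 (camera adjusted p = 5.89e-15 and 1.05e-14; 0.126 and 0.133 with an estimated correlation). Examples were cbd-1, which encodes an eggshell chitin-binding protein (5.37 and 6.24), and chs-1, the chitin synthase gene (4.71 and 5.65). These lists overlap: oma-1, oma-2, mex-3, puf-5 and spn-4 belong to both of the first lists, and rme-2 and gna-2 to the targets and the eggshell list. The medians of these 3 lists stayed positive under all 4 scalings tried and were smallest after cyclic loess, at 1.66 and 2.03 for the earlier targets, 1.45 and 1.62 for the RNA regulators and 1.5 and 1.36 for the eggshell list. After quantile normalization those of the earlier targets were 3.16 and 3.09.

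Cell cycle and embryonic patterning genes followed. Of 40 cell cycle genes 7 and 18 were higher (21 and 23 adjusted over the list alone; medians 1.47 and 1.87; camera adjusted p = 1.26e-14 and 1.66e-15; 0.254 and 0.195 with an estimated correlation). The B-type cyclin genes cyb-2.1 (4.98 and 6.14) and cyb-2.2 (4.63 and 5.70), whose probe sets share sequence, and the replication licensing genes mcm-5 (4.55 and 5.67) and mcm-7 (4.29 and 5.12) led. Of 24 patterning genes 6 and 11 were higher (13 and 14 adjusted over the list alone; medians 1.13 and 1.43; camera adjusted p = 5.85e-13 and 3.35e-12; 0.205 and 0.19 with an estimated correlation). Among them were pal-1, glp-1 and nmy-2, the gene for the non-muscle myosin of early embryos (2.85 and 4.20). The strategy 1 calls of cyb-2.1, cyb-2.2 and nmy-2 ended without any one of MYC replicates 1 and 2 and FLAG replicates 2 and 3. A second cyb-2.2 probe set, 194213_x_at, was called in both strategies. That of nmy-2, 191813_s_at, was called in strategy 2 (2.56, adjusted p = 0.0136) but not in strategy 1 (1.52, adjusted p = 0.203). No member of either list was called lower. The medians of the cell cycle genes were 0.44 and 0.48 after quantile normalization and 0.30 and 0.37 after cyclic loess, and those of the patterning genes 0.18 and 0.36, and 0.09 and 0.44. Among probe sets at log2 5 or more on 3 IP arrays the camera call of patterning ended (adjusted p = 0.218 and 0.136), while cell cycle was called (0.0267 and 0.0159).

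The next lists concerned other germline functions and apoptosis. Of 21 genes for germline stem cells and sex determination 3 and 6 were higher (6 and 7 adjusted over the list alone; medians 0.34 and 0.40, 0.14 and 0.08 after quantile normalization and 0.12 and 0.15 after cyclic loess; camera adjusted p = 6.83e-06 and 5.72e-08; 0.266 and 0.19 with an estimated correlation). Higher in strategy 1 were gld-3 (2.90), glp-1 and lag-1 (2.22), joined in strategy 2 by lst-1 (4.31), tra-2 and fem-3 (3.57), and lip-1 was called lower in strategy 1 by 0.07 near the lowest values of the arrays. Of 29 meiotic genes lab-1 (2.30 and 3.81) and spo-11 (2.12 and 2.76) were higher in both, and sun-1, dsb-1 and him-5 in strategy 2, which makes 2 and 5 (3 and 7 adjusted over the list alone; medians 0.26 and 0.33, negative after quantile normalization; camera adjusted p = 1.97e-07 and 8.08e-07; 0.266 and 0.306 with an estimated correlation). Of 20 genes of P granules and small RNA pathways 3 and 5 were higher (5 and 6 adjusted over the list alone; medians 0.42 and 0.74, -0.04 and 0.07 after quantile normalization and 0.04 and 0.15 after cyclic loess; camera adjusted p = 3.43e-07 and 1.33e-06; 0.28 and 0.319 with an estimated correlation). They were meg-1 (3.88 and 5.22) and mut-16 (3.71 and 4.31) in both, drh-3 in strategy 1, and prg-1, pgl-1 and meg-3 in strategy 2. Of 14 apoptosis genes 3 and 4 were higher (3 and 7 adjusted over the list alone; medians 0.48 and 0.40, 0.07 and 0.00 after quantile normalization and 0.05 and 0.05 after cyclic loess; camera adjusted p = 0.000581 and 0.00269; 0.0947 and 0.133 with an estimated correlation): the engulfment genes ced-6 (3.76 and 3.92) and ced-10 and the p53-like cep-1 in both, and ced-5 in strategy 2. The strategy 1 calls of lab-1 and spo-11 ended without any array of set 1 but FLAG replicate 1, and that of mut-16 without MYC replicate 2. In strategy 2 sun-1 was not called without N2 replicate 3 or tagged replicate 1 or 2. A second sun-1 probe set, 179485_s_at, was called in neither strategy (1.21 and 1.41, adjusted p = 0.322 and 0.144), nor was the second cep-1 probe set given above. That of ced-6, 188052_s_at, was called in both (2.59 and 3.10). The camera calls of these lists ended among probe sets at log2 5 or more on 3 IP arrays, with adjusted p of 0.173 and 0.116 (stem cells), 0.725 and 0.515 (meiosis), 0.361 and 0.374 (P granules) and 0.361 and 0.395 (apoptosis).

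Markers of somatic tissues and sperm were mostly not called. Neuronal genes were dim already in input (median 4.19), so few calls among them say little about enrichment. Genes at log2 5 or more on 3 IP arrays numbered 7 of muscle, 8 of the intestine, 3 of neurons and 19 of collagens and cuticle. In the fit of such probe sets 2, 1, 2 and 0 of them were called higher in strategy 1. In strategy 2 they were 2, 1, 3 and 0. Of all 1627 probe sets in that fit 933 were called higher in strategy 1 and 1149 in strategy 2, so these counts do not by themselves mark a tissue as enriched. Of 21 muscle genes pat-3, which encodes an integrin beta subunit, was higher in both (3.00 and 3.38), and the cofilin gene unc-60 (3.10, adjusted p = 0.0677; 3.95, adjusted p = 0.0124) in strategy 2 but negative after cyclic loess. That makes 1 and 2 (2 and 2 adjusted over the list alone; medians 0.45 and 0.40, negative after quantile normalization and cyclic loess; camera adjusted p = 0.000775 and 0.0254; 0.538 and 0.643 with an estimated correlation). Of 21 intestinal genes the metallothionein gene mtl-2 was higher in strategy 2 (3.49, adjusted p = 0.0237, negative after cyclic loess), so 0 and 1 were called (0 and 1 adjusted over the list alone; medians 0.26 and 0.36, negative after both of these scalings; camera adjusted p = 0.0725 and 0.0226; 0.709 and 0.635 with an estimated correlation). Of 106 neuronal genes nlp-36 (4.11), the synaptobrevin gene snb-1 (3.64) and unc-119 (2.84) were higher and flp-19 was lower by 0.08 in strategy 2, and 0 were called in strategy 1 (0 and 3 higher adjusted over the list alone). By the array maker's suffix the probe sets that represent nlp-36, mtl-2 and unc-60 share sequence with other transcripts. The neuronal medians of -0.03 and -0.04 and the camera direction were negative (adjusted p = 0.197 and 0.0323; 0.709 and 0.531 with an estimated correlation), while the means, 0.07 and 0.08, were positive. Of 146 collagen and cuticle genes 0 were called in either strategy, also adjusted over the list alone (limma, unadjusted p under 0.05: 3 higher and 1 lower in strategy 1, 0 and 7 in strategy 2). Their medians were 0.02 and -0.01. Both were negative after quantile normalization and cyclic loess. Their means were positive (0.08 and 0.06), as was the camera direction (adjusted p = 0.288 and 0.373). The strategy 1 call of pat-3 ended without any one of MYC replicates 1 and 2 and FLAG replicates 2 and 3. A second pat-3 probe set, 191710_at, was called in neither strategy (1.08 and 1.29, adjusted p = 0.237 and 0.0842). Of the other unc-60 probe sets, 171826_x_at (2.18) and 174141_at (4.24) were called in strategy 2, while 192015_s_at (2.32) and 193210_s_at (0.06) were not. In strategy 2 mtl-2 was called only with N2 replicates 1, 2 and 3 and tagged replicates 1 and 2 all present, and unc-60 only with N2 replicates 2 and 3 and tagged replicate 1. The camera call of muscle ended without FLAG replicate 3 (adjusted p = 0.415) in strategy 1 and without tagged replicate 1 (0.0884) in strategy 2, that of the intestine without tagged replicate 1 (0.0884) or N2 replicate 3, and that of neurons without tagged replicate 2 (0.0602). Among probe sets at log2 5 or more on 3 IP arrays most genes left are higher in the FLAG IP, so an unchanged list ranks low. Camera then called collagens (adjusted p = 1.49e-07 and 3.56e-10) and the intestine (0.00225 and 0.0212) lower than the other genes. Muscle (0.361 and 0.317) and neurons (0.584 and 0.329) were not called.

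Of 45 sperm genes 0 were called in either strategy, also adjusted over the list alone (limma, unadjusted p under 0.05: 0 higher and 1 lower in strategy 1, 0 and 4 in strategy 2). A positive change was seen for 24 of them in strategy 1 and for 2 in strategy 2, with medians of 0.02, negative after quantile normalization and cyclic loess, and -0.39, and camera did not call the list (adjusted p = 0.388 and 0.221). Among probe sets at log2 5 or more on 3 IP arrays, where most genes left are higher in the FLAG IP, camera called it lower than the other genes in both (adjusted p = 2.86e-10 and 4.77e-21). The largest changes were positive, those of spe-39 on a probe set of shared sequence (1.09 ± 0.54 and 1.17 ± 0.54, adjusted p = 0.322 and 0.15), which was called in strategy 1 without FLAG replicate 1 (adjusted p = 0.0145). The largest falls were those of msp-76, a major sperm protein gene also on a probe set of shared sequence (-0.45 ± 1.06 and -1.16 ± 1.06, adjusted p = 0.807 and 0.449).

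Among lists of general cell functions, histones had 1 of 26 members higher in each strategy, his-41 (2.83 and 3.36; 1 and 1 adjusted over the list alone). Their medians were 0.13 and 0.16, negative after quantile normalization and, in strategy 1, after cyclic loess (camera adjusted p = 0.000468 and 1.65e-05; 0.489 and 0.338 with an estimated correlation). Of 33 proteasome genes 0 were called (limma, unadjusted p under 0.05: 0 and 1 higher, 0 lower), with medians of 0.47 and 0.45, negative after quantile normalization and cyclic loess (camera adjusted p = 8.63e-05 and 0.00035; 0.608 and 0.635 with an estimated correlation). Their largest changes were those of rpn-3, at 1.36 (adjusted p = 0.322) and 1.73 (adjusted p = 0.144). Of 75 ribosomal protein genes 0 were called, and 0 had an unadjusted p under 0.05 in limma. Their medians were -0.03 and 0.10, and the latter turned to -0.05 with arrays centred on these same genes, and to -2.44 after quantile normalization. The camera direction was positive in both (adjusted p = 0.197 and 0.0438; 0.838 and 0.752 with an estimated correlation), against a negative median and mean in strategy 1. Of 19 nuclear genes of mitochondrial respiration 0 were called, and 0 had an unadjusted p under 0.05 in limma, with medians of 0.14 and 0.10, negative after quantile normalization, cyclic loess and, in strategy 2, ribosomal centring (camera adjusted p = 0.0869 and 0.179). The last 3 of these lists had 0 members called also adjusted over the list alone. The strategy 1 call of his-41 ended without any one of MYC replicates 1 and 2 and FLAG replicates 2 and 3. The camera call of the proteasome in strategy 1 ended without FLAG replicate 3 (adjusted p = 0.422), and that of ribosomal proteins in strategy 2 without N2 replicate 2 or 3 or tagged replicate 1 or 2 (up to 0.424). Among probe sets at log2 5 or more on 3 IP arrays most genes left are higher in the FLAG IP, so an unchanged list ranks low. Camera then called ribosomal proteins (adjusted p = 5.98e-29 and 1.08e-30) and mitochondrial respiration (0.00434 and 0.00762) lower than the other genes, which does not show a fall. Histones (0.142 and 0.109) and the proteasome (0.0863 and 0.109) were then not called. Without FLAG replicate 1 or MYC replicate 3, camera called collagens, intestine, sperm, ribosomal proteins and mitochondrial respiration higher in strategy 1. No camera call of any list passed with an estimated correlation. The directional fry test called these higher in both strategies: earlier targets (adjusted p = 0.00197 and 0.00036), RNA regulators (0.00219 and 0.00036) and eggshell (0.00232 and 0.000473). So it did apoptosis (0.00219 and 0.00178) and patterning (0.026 and 0.00678). In strategy 2 alone fry called cell cycle and stem cells higher and neurons lower (0.00896 each). It called no other list in either strategy and none for their difference.

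**Figure D4:**
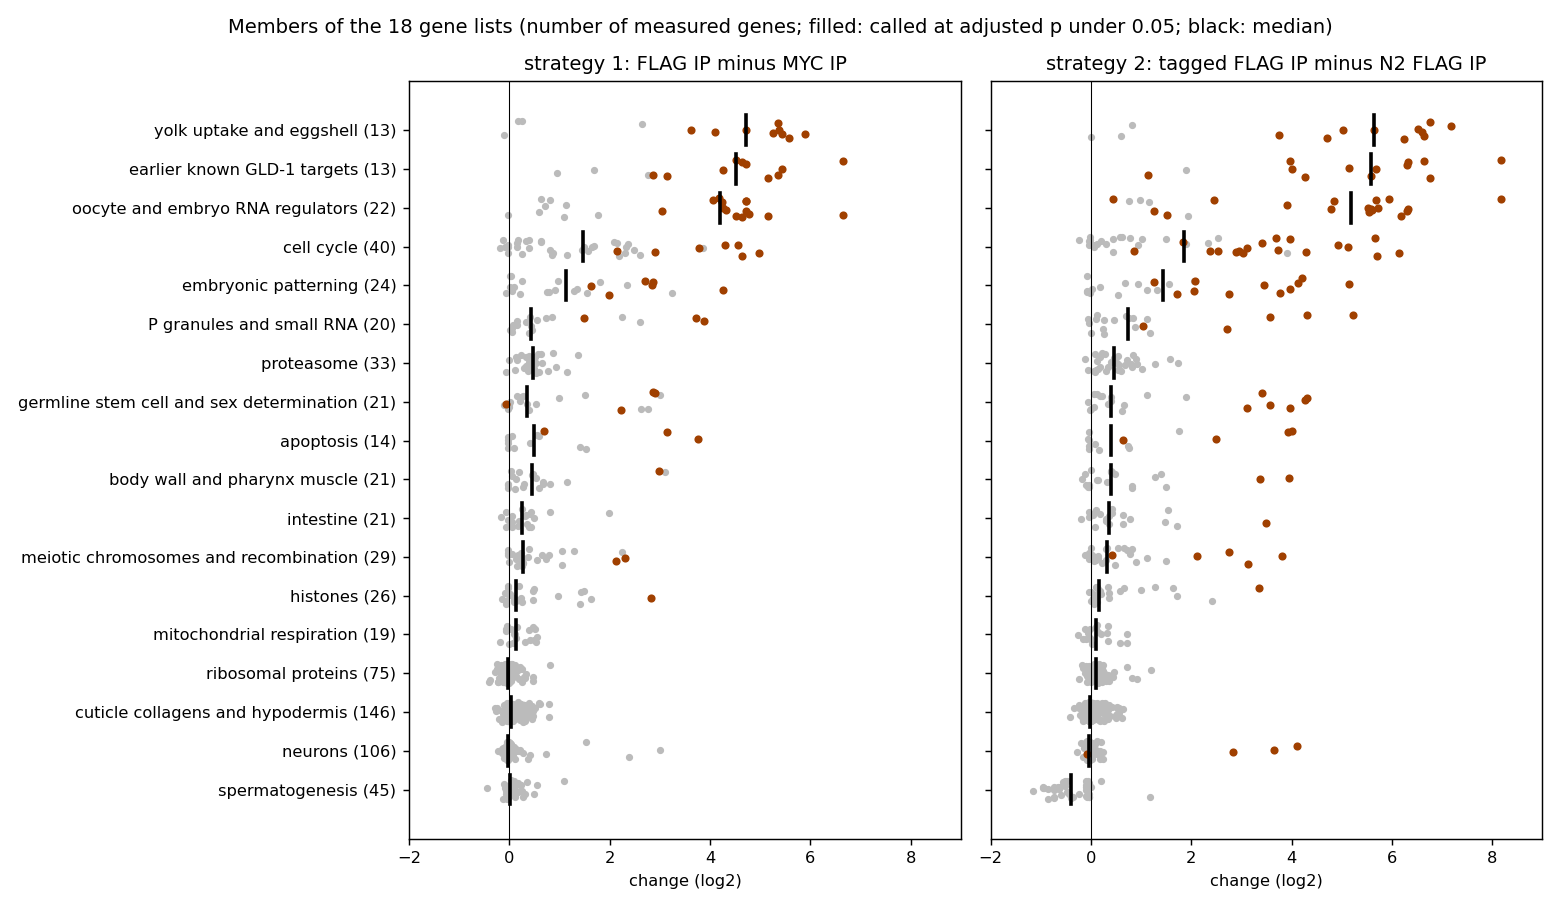
Log2 change of every measured member of the 18 gene lists in strategy 1 (left) and strategy 2 (right), 1 point per gene, filled where the gene was called at adjusted p under 0.05, with a black bar at each median. The medians of the yolk and eggshell genes were 4.71 and 5.65, and those of the sperm genes 0.02 (negative after quantile normalization and cyclic loess) and -0.39.

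The FLAG IPs of the sets, from the same strain with the same antibody, measured what differed between the sets of experiments. Set 1 was lower in 6 probe sets and higher in 0 (limma, unadjusted p under 0.05: 493 lower and 265 higher). Named after their values were seen, these were C30G12.1 (fell by 1.7, adjusted p = 0.0161), T05A12.4 (fell by 1.5, adjusted p = 0.0391), bath-12 (fell by 0.985, adjusted p = 0.00348), F36H5.10, nprt-1 and npp-20. All 6 lay under log2 4 in set 1. The count was 29, 1 and 16 without FLAG replicates 1, 2 and 3 of set 1, and 21, 1 and 10 without tagged replicates 1, 2 and 3 of set 2. It was 0 with the 6 arrays alone, among the 1627 brighter probe sets and after centring on ribosomal protein genes, 22 after quantile normalization, 73 after cyclic loess and 3052 with array weights. The controls, MYC IP of the tagged strain and FLAG IP of N2, differ in antibody, strain and set together. No probe set was called between them (0; limma, unadjusted p under 0.05: 138 higher and 236 lower in the MYC IP). The count was at most 2 with any array left out, 3 after cyclic loess and 644 with array weights.

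The comparison with input asked which transcripts an IP held relative to total RNA, but the IPs also had 10 µg of mouse brain carrier RNA added, and 1/3 of each was labelled against 5 µg of input. The largest falls in the FLAG IP of set 1 were those of the collagen genes dpy-4 (12.72 ± 0.254 in input, 4.57 ± 1.32 in the FLAG IP, SD, n = 3; difference -8.15 ± 0.561 SE, adjusted p = 1.1e-07), col-133 (-7.74 ± 0.637, adjusted p = 5.21e-07) and col-17 (-7.74 ± 0.642, adjusted p = 5.59e-07), all on probe sets of shared sequence. Of the named genes higher in both strategies, some were not called against input and others were called lower. Not called were, among others, oma-2, which differed by 0.31 ± 0.539 (adjusted p = 0.591), gld-1 by -0.69 ± 0.574 (adjusted p = 0.265), gna-2 by -0.44 ± 0.443 (adjusted p = 0.352) and rme-2 by -1.03 ± 0.563 (adjusted p = 0.102). Called lower were, among others, pal-1 (-1.72, adjusted p = 0.00631), glp-1 (-2.13, adjusted p = 0.00304), spn-4 (-2.18, adjusted p = 0.0146), cep-1 (-2.37, adjusted p = 0.0018), pat-3 (-2.87, adjusted p = 9.95e-05), his-41 (-3.02, adjusted p = 8.57e-05) and nmy-2 (-3.51, adjusted p = 9.5e-05). In the MYC IP oma-2 differed from input by -6.34, gld-1 by -6.17, gna-2 by -5.79 and rme-2 by -6.46. Among other named genes higher in both strategies and not called against input in the FLAG IP, this difference was -3.28 for spo-11 and -6.76 for gln-5. In all, 11879 probe sets were lower in the FLAG IP than in input (median 9.63-fold) and 11971 in the MYC IP (13.4-fold), with dpy-4 (-8.53), col-73 (-8.16) and col-17 (-8.10) changed most there. Called higher were 8679 and 8848, of which 8624 and 8788 lay under log2 3 in both groups, where the lowest value of an IP array (2.455 to 2.53) is above that of an input array (2.213 to 2.279). Among the higher calls only 1 reached 2-fold in the FLAG IP, the probe set 183150_s_at with no gene symbol, and 4 did in the MYC IP, 183150_s_at, 183319_at and 2 probe sets of the ribosomal RNA gene rrn-3.1, all under log2 4 (named after their values were seen). With values floored at log2 3 the higher calls numbered 30 and 30, among probe sets at log2 5 or more on 3 arrays 0 and 0, and after quantile normalization 1902 and 2255 with 2616 and 2393 lower. Centring on ribosomal protein genes turned the balance to 16538 higher and 39 lower in the FLAG IP and 15414 and 79 in the MYC IP. With each gene taken by its brightest probe set, the largest higher calls, srab-7 (0.86), amt-3 (0.71) and pqn-29 (0.70) in the FLAG IP and rrn-3.1 (0.78), amt-3 (0.74) and srab-7 (0.64) in the MYC IP, were dim in all groups.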

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

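The test of the MYC control and those of recovery and strain for the sperm genes below were chosen only after the result was seen.

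Enrichment was weaker in strategy 1 than in strategy 2 for 7 lists, by camera on the difference between strategies: RNA regulators of oocytes and embryos (adjusted p = 3.03e-10), earlier known GLD-1 targets (1.54e-06), yolk uptake and eggshell (1.6e-05), cell cycle (0.000139), germline stem cells and sex determination (0.000148), embryonic patterning (0.00209) and histones (0.0442), none of them called with an estimated correlation (adjusted p of 0.703 or more). Among probe sets at log2 5 or more on 3 IP arrays only the RNA regulators (0.021) and the earlier targets (0.00241) were still called. Cell cycle (0.0881), patterning (0.169), germline stem cells (0.169), yolk and eggshell (0.0657) and histones (0.208, with the sign turned) were not. Collagens (4.98e-07), ribosomal proteins (5.79e-10) and sperm (9.83e-24) were called the other way, but only relative to the other genes left. All 1627 probe sets of that level had median changes of 1.74 in strategy 1 and 2.42 in strategy 2. The ribosomal protein genes themselves had the smaller change in strategy 1 (median difference -0.171). All 65 members called higher in either strategy, of the 147 in these lists, had the smaller change in strategy 1, with a median difference of -0.94 (quartiles -1.20 and -0.69). These members come from lists chosen by this same difference in the same arrays. Their shared sign therefore describes the pattern and is no further support for it. A higher background of these transcripts in the MYC control is argued against, since they differed between MYC and N2 IPs by a median of 0.0444 (quartiles -0.138 and 0.174), while the FLAG IPs of the sets differed by -0.951. A single factor on all enriched transcripts may account for it: other called probe sets gave a slope of 0.766 of strategy 1 on strategy 2, from which the members lay 0.0652 away (quartiles -0.17 and 0.275). The dim FLAG replicate 1 of set 1 stays open as a part of the cause, since without it the median difference was -0.35 (quartiles -0.541 and -0.166) and 1 of the 7 lists, the RNA regulators, was still called (adjusted p = 0.00247), and no biological explanation was tested. Without MYC replicate 3 cell cycle, patterning and histones were not called (adjusted p = 0.169, 0.312 and 0.891), without tagged replicate 1 of set 2 patterning and histones were not (0.102 and 0.681), and histones were not without N2 replicate 3 (0.243) or tagged replicate 2 (0.0637).

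Sperm transcripts differed between strategies too (camera adjusted p = 0.00278; 0.886 with an estimated correlation), though not without MYC replicate 1 (0.39), FLAG replicate 3 of set 1 (0.618, with the sign turned) or N2 replicate 1 (0.0652). All 22 sperm genes at log2 5 or more on 3 IP arrays, each an msp gene, were lower in the tagged FLAG IP of set 2 (median -0.724, 0 called), against 9 of 22 lower in strategy 1 (median 0.0372), and under quantile normalization and cyclic loess the list median was negative in both strategies. Lower recovery of all background RNA in that IP is argued against, since ribosomal protein transcripts had a median change of 0.0994 in strategy 2. Less sperm RNA in the tagged strain was examined by the level of these genes relative to ribosomal protein genes. In the 6 IPs of set 1 this level was -0.212 from that of the N2 IPs. N2 was measured in set 2 only, however, and the tagged FLAG IPs differed between the sets. Their levels were -1.04, -1.22 and -1.55 in set 1 and -1.91, -2.05 and -1.93 in set 2. A strain difference therefore cannot be told apart from a set difference by this comparison. The level was -1.02 ± 0.123 in the N2 IPs (SD, n = 3) and -1.96 ± 0.0718 in the tagged IPs of set 2 (exact permutation p = 0.1, two-sided, the smallest these 6 arrays can give). Cross-hybridization of near-identical msp copies cannot be told apart from a real change, because 0 of the 22 have a probe set of unshared sequence, and fewer sperm in the tagged worms of set 2 alone stays open, untested.

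Other splits of the arrays were counted for each comparison, and 6 arrays make only 10 splits, too few for a share under 0.05. Strategy 1 gave 556 called probe sets and 2 of 10 splits, the real one included as in all counts here, gave as many, the highest other 10259. That split put MYC replicates 1 and 2 with FLAG replicate 1 against MYC replicate 3 with FLAG replicates 2 and 3, which points to a structure of set 1 along the ribosomal protein background, 5.749 to 7.714 on the former arrays and 7.985 to 9.847 on the latter. Strategy 2 gave 1272 (1 of 10, highest other 1), the FLAG IP sets 6 (3 of 10, highest other 57), the controls 0 (10 of 10, highest other 1), FLAG IP against input 20558 (1 of 10, highest other 0), MYC IP against input 20819 (1 of 10, highest other 0), the lists called in strategy 1 12 (6 of 10, highest other 18) and in strategy 2 15 (1 of 10, highest other 14). The other splits called a median of 12 lists in strategy 1 and 11 in strategy 2, so camera at a correlation of 0.01 calls many lists on these arrays whatever the grouping. Of 100 drawn splits of both sets, 2 gave as many as the 526 probe sets higher in both strategies. This small share rests on set 2, where other splits called at most 1 probe set. Set 2 alone has only 10 splits, and crossing them with those of set 1 adds no evidence about set 2. The highest other, 5092, was the same uneven split of set 1 with the real groups of set 2. The drawn splits therefore cannot exclude chance for either set. For the difference between strategies 100 of 100 drawn splits gave at least its 0 probe sets (highest other 18) and 73 of 100 at least its 8 lists (highest other 17), so chance is not excluded for either.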

How the results depend on the processing

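The filter at log2 5 with the replicate block, the same filter with each array left out, and values floored at log2 3 were tried only after the data were seen. Unless a value or the construction of a setting shows it, the cause was not tested. Signal over background limits these results: most probe sets of an IP array lie near its lowest value. The lower calls of the strategies in the reported fit mostly sit there, unlike those against input. Counts are given for strategy 1 higher and lower (S1), strategy 2 higher and lower (S2), higher and lower in both (B), the difference between strategies (D), the FLAG IP sets (F), the controls (C) and, against input, FLAG and MYC IP higher and lower. Counts left out stayed within 1.5 times the reported one. More probe sets were higher than lower in S1 and S2 in each setting run, except S1 and S2 with array weights, S2 with the block, and both with the 6 arrays alone. D cannot come from 6 arrays, and F and C, which lie across the sets, were not run with the block.

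Only the 6 arrays of a comparison: S1 0 and 0, S2 2601 and 6460, B 0 higher, F 0. All 15 arrays: S1 2 lower, S2 6 lower, D 2. Filter at log2 5, which leaves 1627 probe sets of the IPs: S1 933 and 0, S2 0 lower, B 928 higher (658.9 for independent lists; 487 of the 526 among them), F 0, FLAG against input 0 and 7414, MYC 0 and 7537. Filter at log2 7: S1 356 and 0, S2 372 and 0, F 0, input 0 and 4123, 0 and 4215. Quantile normalization: S1 350 lower, S2 579 lower, B 282 lower, D 2, F 22, input 1902 and 2616, 2255 and 2393. Array medians: S1 6 lower, S2 16 lower, F 3. Ribosomal centring, which shifts the median of strategy 2 by -0.147: S1 199 and 0, S2 385 and 0, B 191 higher, F 0, input 16538 and 39, 15414 and 79. Cyclic loess: S1 366 lower, S2 598 lower, B 336 lower, D 3, F 73, C 3, input 4840 and 7289, 4441 and 6349. Trend and robust: S1 7 lower, S2 87 lower, F 2. Adjusted p under 0.01: S1 209 and 2, S2 639 and 8, B 203 higher, F 1. At least 2-fold: S1 0 lower, S2 0 lower, F 2, input 1 and 4 higher. Treat: S1 313 and 0, S2 714 and 0, B 306 higher, F 0, input 1 and 3 higher. 1 probe set per gene and the gene mean: D 1 each. Without shared sequence, which removes 6711 probe sets: S1 300, S2 644, B 289 higher, D 1, input 6893 and 6923 lower. Array weights, which did not converge and gave 1 array a weight of 6920: S1 6224 and 12432, S2 3195 and 7995, B 2871 and 7557, D 1388, F 3052, C 644. Floor at log2 3: S1 356 and 1, S2 5 lower, B 348 and 1, D 1, input 30 and 30 higher. Spearman gave 0.529 for the relation of the strategies.

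Each array left out: S1 196 to 2090 higher and 4 to 442 lower, S2 669 to 1011 and 15 to 54, B 193 to 1688 and 0 to 33, D 0 to 4, F 1 to 29, C 0 to 2. The highest S1, B and F came without FLAG replicate 1 of set 1, and the highest D without it or without tagged replicate 1 or 3 of set 2. With the filter at log2 5, S1 was 643 to 1210, S2 1016 to 1204 and B 643 to 1188.

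The replicate number as a block (S2 2626 and 5529 and B 3 lower; with the filter at log2 5 S1 1215 and 0, S2 19 lower, B 1211 higher and D 19) assumes pairs that the labels do not state and the arrays show only in part. Ribosomal protein medians followed the replicate number in both groups of each set (6.511, 7.714 and 9.396 for MYC, 5.749, 7.985 and 9.847 for FLAG; 7.977, 7.111 and 6.436 for N2, 7.806, 7.43 and 6.729 for tagged FLAG). Correlations of equal numbers were 0.80, -0.07 and 0.87 in set 1 and 0.51, 0.037 and 0.52 in set 2, and not every array correlated best with its own number. Lists called only with the block were collagens (adjusted p = 0.0237), intestine (0.00174) and mitochondrial respiration (0.00924) higher in strategy 1, and mitochondrial respiration higher (0.046) and sperm lower (0.000445) in strategy 2. For the difference between strategies they were P granules (0.0189), intestine (0.00646) and ribosomal proteins (0.0037), each with the smaller change in strategy 1.

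Lists that turned to a lower change than the other genes with the filter at log2 5, where most genes left are higher in the FLAG IP, had adjusted p in strategies 1 and 2 of 0.361 and 0.317 (muscle), 1.49e-07 and 3.56e-10 (collagens), 0.142 and 0.109 (histones), 0.00225 and 0.0212 (intestine), 0.00434 and 0.00762 (mitochondrial respiration), 0.0863 and 0.109 (proteasome), 5.98e-29 and 1.08e-30 (ribosomal proteins) and, in strategy 1, 2.86e-10 (sperm). Sperm, already lower in strategy 2 but not called, was called lower there (4.77e-21). Neurons turned positive in both (0.584 and 0.329). The calls of patterning (0.218 and 0.136), stem cells and sex determination (0.173 and 0.116), meiosis (0.725 and 0.515), P granules (0.361 and 0.374) and apoptosis (0.361 and 0.395) ended with this filter. With each array left out, ribosomal proteins ranged from 8.78e-06 to 0.348 and sperm from 0.00793 to 0.736 in strategy 1. Both turned negative without FLAG replicate 3 of set 1 (4.6e-05 and 0.00808).

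Named genes that turned negative after quantile normalization were, in strategy 1, atp-2 (-1.42), atp-4 (-1.39), col-133 (-1.22), col-17 (-1.24), col-73 (-1.16), dpy-4 (-1.06) and rps-10 (-1.12), and in strategy 2 atp-2 (-1.81), atp-4 (-1.61), col-17 (-1.28), col-73 (-1.70), rpl-26 (-1.23) and rps-10 (-1.60). After cyclic loess they were atp-2 (-2.26), atp-4 (-1.69), rpl-26 (-2.33) and rps-10 (-2.45) in strategy 1, and atp-2 (-2.82), atp-4 (-2.16), col-17 (-1.38), col-73 (-1.70), mtl-2 (-0.98), rpl-26 (-3.09), rps-10 (-3.06) and unc-60 (-0.279) in strategy 2. ZK1128.3 turned to -0.0411 in strategy 1 with array weights. The search for motifs in untranslated regions was not run.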

Other observations

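The tests of the mitochondrial transcripts, the input level used for chromosomes and the gene classes were chosen only after the results were seen.

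Transcripts of the mitochondrial genome, which are made and translated inside mitochondria, had positive changes in both strategies, with no test of the set. Of 8 on the array 7 were detected in input, and all 7 had a higher mean in both strategies, with medians of 1.78 and 2.02. ND4 was 9.16-fold higher in strategy 1 (3.20 ± 0.75, adjusted p = 0.0716) and 15.6-fold in strategy 2 (3.96 ± 0.75, adjusted p = 0.0149), COX2 6.85-fold and 8.56-fold (adjusted p = 0.117 and 0.043) and COX3 5.8-fold and 10.2-fold (adjusted p = 0.148 and 0.0264). That makes 0 and 3 called, or 4 and 5 among probe sets at log2 5 or more on 3 IP arrays. All 1627 probe sets of that level had medians of 1.74 and 2.42, and 89.74% of them a higher mean in both strategies, close to the values of the mitochondrial transcripts. The sign is not stable: after quantile normalization COX1, CYTB and ND1 were negative in both strategies and ATP6 in strategy 2, and after cyclic loess all 7 were negative in both. A higher recovery of all abundant RNA alike is argued against by the ribosomal protein genes, whose larger median change was 0.0994. They are a single class, though. Genes at log2 10 to 12 in input had median changes of 0.654 and 0.891 in strategies 1 and 2, and those at 12 or more 0.0836 and 0.152. A higher recovery of part of the abundant RNA is therefore not excluded. Shared probe sequence is argued against by the 6 transcripts on probe sets of unshared sequence, with medians of 2.16 and 2.56. A binding of GLD-1 to these transcripts, or of mitochondria to the tagged complexes in the extract, stays open, untested.

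The share of genes higher in both strategies depended on the level in input. It was 0 of 9347 genes under log2 4 in input, 0.367% of 2450 at 4 to 6, 4.22% of 2700 at 6 to 8, 11.4% of 1928 at 8 to 10, 11% of 519 at 10 to 12 and 2.3% of 174 at 12 or more. Among genes at log2 8 or more in input, 79 of 550 on chromosome I were higher in both, 14.4%, against 9.82% on all other chromosomes. On the X chromosome the share was 7.3% of 178, against 11% on all others. The odds ratio was 1.54 for chromosome I (Fisher's exact p = 0.00318, two-sided; 0.0191 adjusted over 6 chromosomes) and 0.636 for X (exact p = 0.133; adjusted 0.314). Fisher's test counts genes as independent, which genes called on the same arrays are not. Its p-values therefore describe this list of genes and not the spread between replicates.

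Gene classes, read from the letters of gene names, were compared among 6542 genes at log2 5 or more in input, of which 403 (6.16%) were higher in both strategies. None of 183 classes passed the correction (0 at adjusted p under 0.05). The smallest p-values were those of the puf genes, with puf-3, puf-5, puf-7 and puf-11 higher of 7 (Fisher's exact p = 0.000428, adjusted 0.0745), and of the mcm genes, with mcm-3, mcm-4, mcm-5 and mcm-7 higher of 8 (exact p = 0.000814, adjusted 0.0745). Both classes also hold members of the fixed lists. Of 71 col genes 0 were higher in both. Sequence motifs of GLD-1 in untranslated regions were not analysed here.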
